A study of Mus musculus with 8 samples.

How the data were processed

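RAW 264.7 mouse macrophage-like cells were treated with a bacterial strain or left untreated, and 8 two-colour arrays on 2 slides were analysed, 2 for *L. acidophilus*, 3 for *B. clausii* and 3 for *B. bifidum*. Per the labels, RNA of treated cells was labelled with Cy5 and RNA of time-matched untreated cells with Cy3 on every array. The labels name separate replicates, and the design text calls them biological, but nothing ties an array to its own culture. The p-values therefore measure only the spread between these arrays, which may be technical. No untreated sample was hybridised as a sample of its own, so the spread of the untreated cells among themselves was left out.

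The deposited scanner files hold spot and background brightness as linear intensity, per the file headers from Agilent Feature Extraction 10.7.3.1. The submitters' processing notes name version 10.5.1.1, and the difference was not resolved. The same files hold the software's processed intensity, background-subtracted and dye-normalized within the array, per the file headers, and its log10 ratio of Cy5 over Cy3. The authors' deposited value table was set against these columns. It equalled the scanner's log10 ratio on every array to within 0.005, so its scale and direction are known. Its medians were 0 on all arrays, and 18.0% to 48.4% of its values were exactly 0.

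Files were read with limma 3.58.1 in R 4.3.3. The median signal of each spot was used in place of the planned mean signal, which was not among the columns of the files used here. The background was corrected with normexp (offset 50) over all spots, and log2 ratios were normalized within each array by loess with control spots at weight 0. Spots marked as outliers were removed and saturated spots were kept. Each array had 45018 features, of which 1639 were controls and 43379 belonged to 41174 distinct probes, 245 of them with 10 spots each. Spots of a probe were averaged. A probe was kept where it was well above background in at least 1 channel on at least 2 arrays, which 28598 probes were.

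Probes were named through the transcript accessions in the files, matched without versions to a RefSeq gene table of assembly GRCm38.p6. That table was used for names only, and no coordinates are given, since the files name another build. Names were found for 29455 of the probe features and not for 13924. Of the kept probes, 21767 had a gene. Each of the 15296 genes was represented by its probe with the highest mean brightness. For 5033 genes with several probes, the text says where the probes of a named gene disagreed. A value was missing on some array for 297 genes.

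Log2 ratios were fitted with limma (lmFit and eBayes) with a mean per strain over all 8 arrays, tested against 0 for each strain and between strains, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists, 30 in all with 6 for other cell types, were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Fry asks whether a list moves on balance in a direction and does not compare it with other genes. Random lists of the same size, matched on brightness, numbered 10000. The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

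The named genes were 12 fixed genes of the inflammatory response, the 8 largest rises and 8 largest falls (5 and 5 between strains) among genes that passed with the same sign on all arrays of the strain (between strains, with arrays that did not overlap), and up to 3 passing members with the smallest p from each list that passed. Names of clones, expressed sequence tags and predicted genes were left out. Where fewer than 5 genes passed, the 5 with the smallest p in each direction were named as not passing. Members of small counts between strains were also named where a missing array kept them outside the rule, after their values were seen.

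The steps were tested on simulated data with 200 changed genes among 14999. For *B. clausii* the fit recovered 62.7%, 94.0% and 98.5% of genes changed by a log2 ratio of 0.5, 1 and 2 and called 8 unchanged genes, and for *B. bifidum* 62.7%, 83.6% and 100%, with 11 unchanged genes called. For *L. acidophilus* it recovered 37.3%, 88.1% and 97.0%, with 4 unchanged genes called. Between *B. clausii* and *B. bifidum* the shares were 28.4%, 80.6% and 97.0%. These simulations held no slide effect.

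The alternatives were no background correction, the scanner's processed signals, the deposited matrix, median centring in place of loess, Aquantile between arrays, no filter and a strict filter on dim probes, the mean of a gene's probes, each probe on its own, Cy5 alone, an intensity trend with robust eBayes, a minimum log2 ratio of 1, an estimated correlation in camera, the replicate number as a block, the slide as a block, only the strains compared, and each array left out in turn. Fits of slide 1 or slide 2 alone, averaging of the arrays of a strain on a slide, and leaving out saturated spots were chosen after seeing the data.

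Pairs of arrays of the same strain on the same slide were checked for being a single sample hybridised again, by comparing their ratios over probes with repeated spots with the noise between spots. The check was run in several forms after the counts of called genes had been seen. For *B. clausii* replicates 1 and 2, the variance between arrays over that between spots was 1.44 over 88 probes and 1.71 over 100 probes with spots paired by place, and 0.452 unpaired. Both paired ratios had a p under 0.05 by an F test. For the *L. acidophilus* arrays the paired ratios were 2.04 and 1.93 and the unpaired ratio 1.41, and for *B. bifidum* replicates 1 and 2 they were 6.32, 7.33 and 3.45. All arrays were kept as replicates, with the averaged fit as an alternative. Over all probes the ratios of the scanner's processed signals correlated at r = −0.363 between *L. acidophilus* replicate 2 and *B. clausii* replicate 1. The scanner's log10 ratios of these arrays correlated at r = 0.016. After loess the lowest correlation between arrays was −0.07. The labels state the dyes, so the direction was kept.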

Results

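Gene expression was measured in RAW 264.7, a mouse macrophage-like line from BALB/c mice, after 6 hours with *Lactobacillus acidophilus*, *Bacillus clausii* or *Bifidobacterium bifidum*, each added at a multiplicity of infection of 1. All 3 bacteria are used as probiotics. Each array was a two-colour Agilent array on which RNA of the treated cells was labelled with Cy5 and RNA of time-matched untreated cells with Cy3, so that each array gave a ratio of treated over untreated cells. There were 2 arrays for *L. acidophilus*, 3 for *B. clausii* and 3 for *B. bifidum*. The submitters' design text states 3 biological replicates per condition, and 2 arrays of *L. acidophilus* were analysed here. Dyes were never swapped, so a probe that takes up the dyes unequally was not corrected in the ratios against untreated cells. A dye effect that is the same on every array cancels between strains, and one that differs between arrays does not.

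The arrays came from 2 slides. Slide 1 held both *L. acidophilus* arrays, *B. clausii* replicate 3 and *B. bifidum* replicate 3, and slide 2 held replicates 1 and 2 of *B. clausii* and of *B. bifidum*. On 7 arrays, 22713 to 28015 probes were well above background in at least 1 channel. *B. clausii* replicate 3 had 13373 such probes, its grid was rated not good by the scanner software, and the spread between its repeated spots was 72.5% in Cy5 and 67.4% in Cy3. Slide 1 was scanned with an extended range and had no saturated spot. On slide 2 the scanner reached its ceiling for 82 genes, of which 35 were saturated in both channels on at least 1 array. Where both channels were at the ceiling, the log2 ratio carries only the adjustment for dye bias, so single genes saturated in this way with a strain are given only their slide 1 values for that strain. Where Cy3 alone was at the ceiling, the ratio on that array is an upper bound. The number of arrays limits the precision of every value.

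Arrays resembled their slide more than their strain. Across 6878 bright genes, which are not independent replicates, log2 ratios of *B. clausii* or *B. bifidum* on slide 2 correlated with those of the same strain on slide 1 at r = −0.03 to 0.03. Within slide 2, arrays of the same strain correlated at r = 0.96 to 0.98 and arrays of different strains at r = 0.48 to 0.50. Within slide 1, the *L. acidophilus* arrays correlated at r = 0.77 and arrays of different strains at r = 0.60 to 0.76. Results over all 8 arrays are therefore followed by values with the slide in the model and by values within a slide. The fits within a slide were chosen after seeing the data.

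**Figure D1:**
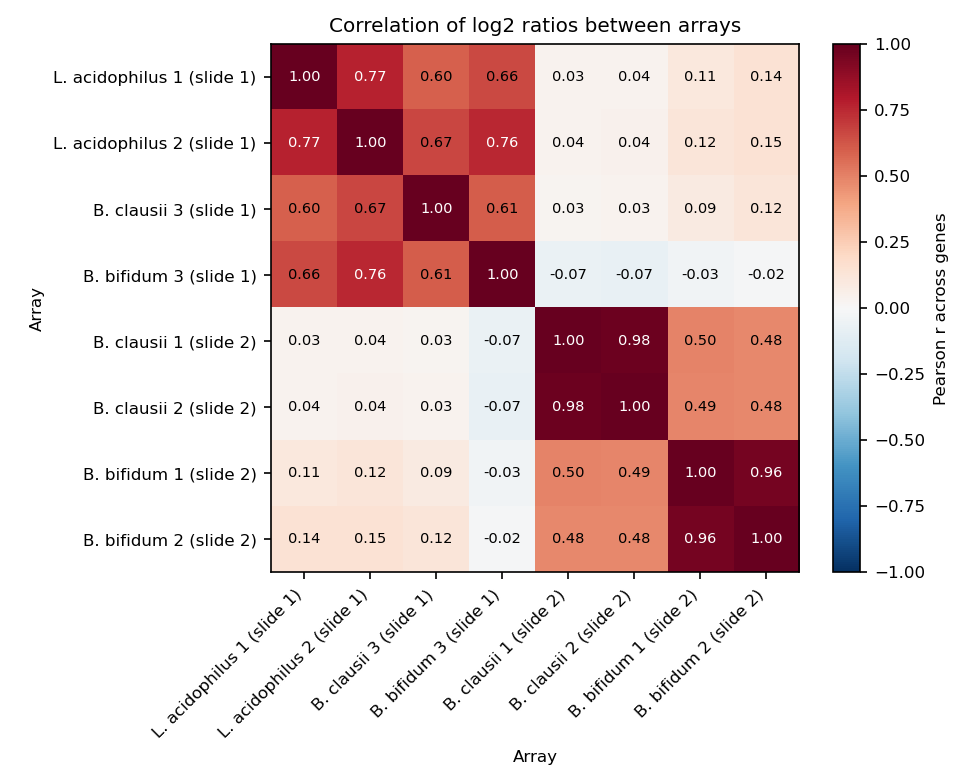
Heat map of Pearson's r across 6878 bright genes between the log2 ratios (Cy5 over Cy3) of each pair of the 8 arrays, with arrays named by strain and replicate. Pairs on the same slide lie between 0.48 and 0.98, and pairs on different slides between −0.07 and 0.15.

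The comparison of *L. acidophilus* with untreated cells asked which transcripts differ after 6 hours with this bacterium. No gene passed. Rpl41, a ribosomal protein gene, had a log2 ratio of 0.96 ± 0.10 (SE, n = 2, adjusted p = 0.0833), and Plin2, which coats lipid droplets, one of 0.77 ± 0.11 (SE, n = 2, adjusted p = 0.314). Ptma, which encodes the nuclear protein prothymosin alpha, had 0.80 ± 0.13, Lrrc58 0.71 ± 0.08 and Fam199x 0.46, and the probes of Lrrc58 disagreed. The lowest ratios with small p were those of the zinc transporter Slc39a5 (−0.76 ± 0.09) and the histone H2A genes H2ac15 (−0.64 ± 0.08) and H2ac13 (−0.61 ± 0.07), each with an adjusted p of 0.0833 (SE, n = 2). Atp5mpl had −0.56 and Tmem256 −0.47. Limma called 0 of 15296 genes, and 1106 had an unadjusted p under 0.05. With the slide as a block, 155 genes rose and 265 fell, but the strain had no slide 2 array, so its slide effect was taken from the other strains. Within slide 1, limma called 0 genes, with 3921 at an unadjusted p under 0.05. Leaving out *L. acidophilus* replicate 1 gave 59 calls, replicate 2 gave 3, and leaving out *B. clausii* replicate 3 gave 6.

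Genes of the inflammatory response to bacteria did not pass with *L. acidophilus*. The chemokine gene Ccl2 had a log2 ratio of 0.44 ± 0.08 (SE, n = 2, adjusted p = 0.318). The cytokine genes Il1b and Il6 had −0.44 ± 0.13 and −0.39 ± 0.13 (SE, n = 2), each with an adjusted p of 0.664. Tnf had −0.19, the interferon-inducible chemokine gene Cxcl10 −0.28 and the prostaglandin synthase gene Ptgs2 −0.13. The receptor genes Tlr2, Tlr4 and Cd14 had 0.10, 0.24 and 0.18, and Il10, Nos2 and Arg1 had 0.01, 0.07 and 0.16. Both arrays lay on slide 1, so these ratios are relative to the untreated channel of that slide. There Il1b, Ptgs2, Ccl2, Il6, Nos2 and Tnf were brighter than in the untreated channel of slide 2, and Tlr2 and Tlr4 were dimmer, as given below. Among 18 measured proinflammatory cytokines and enzymes the median was −0.09 (adjusted p = 0.0905), and no member passed. The lists of osteoclast, dendritic cell, neutrophil, lymphocyte, fibroblast and epithelial markers did not pass either (adjusted p = 0.588 to 0.976).

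Ribosomal proteins were the 1 gene list that camera called with *L. acidophilus* over all 8 arrays. Their median log2 ratio was 0.26 over 37 measured members, of which 0 rose and 0 fell over all genes, and 1 rose adjusted over the list alone. Camera gave the list an adjusted p of 2.84e-05, which became adjusted p = 0.799 with an estimated correlation. Fry gave an unadjusted p of 0.0493. Both arrays lay on slide 1, where no spot was saturated. From the scanner's processed signals and from the deposited matrix the median was 0.060 and 0.059, and camera called 0 lists, with 2 and 8 at an unadjusted p under 0.05. It was 0.98 with median centring, or 0.84 relative to all genes. With the slide as a block, whose effect came from the other strains, the median was 0.40, and the interferon-stimulated genes (median −0.23), the lysosome list (−0.16) and the glycolysis and hypoxia list (0.14) passed too (adjusted p = 0.679 with an estimated correlation for each of the 4). On the strain's own arrays the interferon-stimulated genes had medians of 0.019 and −0.015 and the lysosome list −0.036 and −0.047. Without the 22 members saturated on slide 2, the median of the other 15 was 0.17 and the call ended (adjusted p = 0.628).

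The comparison of *B. clausii* with untreated cells gave 330 genes that rose and 396 that fell. The largest rise was that of Chac1, which degrades glutathione and is induced by the integrated stress response, with a log2 ratio of 2.26 ± 0.43, or 4.8-fold (SE, n = 3, adjusted p = 0.0396). The adhesion receptor gene Adgre5 rose by 1.76 ± 0.41, the glucose transporter gene Slc2a1 by 1.05 ± 0.13 and Adm, which encodes the peptide adrenomedullin, by 1.05 ± 0.16 (SE, n = 3). Crip2 rose by 1.26 ± 0.19 and Arglu1 by 1.07 ± 0.21 (SE, n = 3). Ptma rose by 1.18 ± 0.10 (SE, n = 3, adjusted p = 0.00404), 2.26-fold, and its ratio was above 0 on all 8 arrays of the 3 strains. These arrays had the same dye orientation, so a dye effect of its probe cannot be told apart from a response. In cells treated with *B. bifidum* the probes of Ptma disagreed.

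Among the falls with *B. clausii*, the carbonic anhydrase gene Car6 had a log2 ratio of −1.30 ± 0.29 and the iron transporter gene Slc11a2 one of −1.18 ± 0.25 (SE, n = 3), though the probes of Slc11a2 disagreed. Igsf6 and the phosphatase gene Ptpn14 both had −1.07 ± 0.24. Tnfaip2, a gene induced by tumour necrosis factor, had −1.01 ± 0.16 and the interferon-stimulated gene Parp14 −0.998 ± 0.22. Bsg, a cell surface glycoprotein gene, had −1.003 ± 0.22 and Atp6v1e1, a subunit gene of the proton pump that acidifies lysosomes, −0.996 ± 0.19. Of the 726 calls, 698 had the same sign on all arrays of the strain and 20 lay beyond a log2 ratio of 1 in size.

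The values of *B. clausii* came mostly from slide 2. Chac1 had log2 ratios of 3.11 and 3.19 there and 0.49 on replicate 3, Adgre5 had 2.63, 2.59 and 0.07, and Ptma had 1.33, 1.34 and 0.86. With the slide as a block, which takes the difference between slides out of the spread, 1644 genes rose and 2207 fell. Of these 3851 calls, 2871 had the same sign on all arrays of the strain. Within slide 2, 3925 rose and 4618 fell. Within slide 1 the strain had 1 array and the spread came from the 2 *L. acidophilus* arrays alone, so no count is given. The count was 0 without replicate 1 or 2 (limma, with 1939 and 1946 genes at an unadjusted p under 0.05) and 5486 without replicate 3. It was 6 without either *L. acidophilus* array, 7 without *B. bifidum* replicate 1, 6 without replicate 2 and 1711 without replicate 3. Among the genes named here for *B. clausii*, only Ptma and Npc2 passed without each of the *L. acidophilus* and *B. bifidum* arrays in turn, and neither passed without *B. clausii* replicate 1 or 2. Npc2 had no value on *B. clausii* replicate 3, so for this strain it was measured on slide 2 alone. Of the calls, 20 were of genes with saturated spots on slide 2, 17 of them rises. Limma called 0 genes with median centring, 0 with only the arrays of *B. clausii* and 0 with same-slide arrays averaged, at 4861, 3031 and 695 genes with an unadjusted p under 0.05. It called 194 without background correction, 44 from the scanner's processed signals, 69 from the deposited matrix and 79 with a robust intensity trend.

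No gene of the fixed inflammatory set passed with *B. clausii* over all 8 arrays. Tlr2, a receptor for bacterial lipoproteins, had a log2 ratio of −0.66 ± 0.16 (SE, n = 3, adjusted p = 0.0506), Cxcl10 had 0.66 ± 0.22 (adjusted p = 0.0892) and Ptgs2 0.43 ± 0.18 (adjusted p = 0.146). Within slide 2 these passed, with 1.09 ± 0.05 for Cxcl10, 0.79 ± 0.04 for Ptgs2 and −0.94 ± 0.04 for Tlr2 (SE, n = 2), and Tlr4 fell by 0.35 ± 0.04. On replicate 3, Cxcl10 had −0.19, Ptgs2 −0.27, Tlr2 −0.11 and Tlr4 0.22. Ccl2 had 0.17 ± 0.06, Il1b −0.23 ± 0.11 and Tnf −0.09 ± 0.08 over all arrays, and Il6, Il10, Nos2, Tlr4, Cd14 and Arg1 lay between −0.16 and 0.06. The lists of proinflammatory cytokines and enzymes (median −0.05, adjusted p = 0.869) and chemokines (−0.04, adjusted p = 0.715) did not pass.

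The lysosome and phagosome list shifted down with *B. clausii*, although most members did not pass. Of 43 measured members 0 rose, 10 fell and 33 did not pass, and 28 fell adjusted over the list alone. The median was −0.42 (camera adjusted p = 2.47e-10, and adjusted p = 0.402 with an estimated correlation). Npc2, which carries cholesterol out of lysosomes, had a log2 ratio of −1.10 ± 0.08 (SE, n = 2, adjusted p = 0.00404), the alpha-galactosidase gene Gla −0.78 ± 0.13 and the membrane protein gene Lamp2 −0.57 ± 0.10 (SE, n = 3), with disagreeing probes for Lamp2. The value of Npc2 came from slide 2 alone, since it was missing on replicate 3. Within slide 2, 40 members fell and 1 rose, among them Psap at −1.59 ± 0.05 and the acid lipase gene Lipa at −1.58 ± 0.05 (SE, n = 2). The list median was −0.59 on both slide 2 arrays and −0.03 on replicate 3, and with the slide as a block it was −0.37 (adjusted p = 8.74e-10, and adjusted p = 0.504 with an estimated correlation).

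The list of genes induced by type I interferon also shifted down with *B. clausii*, with few members past the threshold. Of 41 members 0 rose, 4 fell and 37 did not pass, and 23 fell adjusted over the list alone. The median was −0.37 (adjusted p = 6.8e-08, and adjusted p = 0.402 with an estimated correlation). The GTPase gene Irgm1 had a log2 ratio of −0.59 ± 0.08 and the antiviral gene Rsad2 −0.48 ± 0.10 (SE, n = 3). Within slide 2, 35 members fell and 3 rose, with Oas2 at −1.75 ± 0.04 and Zbp1 at −1.60 ± 0.04 (SE, n = 2). Medians were −0.62 and −0.59 on slide 2 and 0.01 on replicate 3, and −0.28 with the slide as a block (adjusted p = 5.1e-07, and adjusted p = 0.504 with an estimated correlation).

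The antigen presentation and macrophage identity lists shifted down with *B. clausii*. In the antigen presentation list 2 of 25 members fell, 23 did not pass and 5 fell adjusted over the list alone (median −0.25, adjusted p = 0.00116, and adjusted p = 0.402 with an estimated correlation). Its calls were Cd74, the invariant chain of class II molecules, at −0.88 ± 0.18 and the immunoproteasome gene Psmb8 at −0.47 ± 0.09 (SE, n = 3). Of 21 macrophage identity genes 2 fell, 19 did not pass and 11 fell adjusted over the list alone (median −0.36, adjusted p = 0.002, and adjusted p = 0.402 with an estimated correlation). Mpeg1, which encodes a pore-forming protein of phagocytes, had −0.85 ± 0.20 and the transcription factor gene Cebpa −0.29 ± 0.06 (SE, n = 3), with disagreeing probes for Cebpa. The medians on replicate 3 were 0.01 for each list. A slide block gave −0.23 (adjusted p = 0.005) and −0.29 (adjusted p = 0.00186), with adjusted p = 0.504 for each with an estimated correlation.

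The cholesterol biosynthesis list shifted up with *B. clausii*, although most members did not pass. Of 25 members 4 rose, 0 fell and 21 did not pass, and 15 rose and 1 fell adjusted over the list alone. The median was 0.32 (adjusted p = 7.26e-06, and adjusted p = 0.402 with an estimated correlation). Sqle, which makes squalene epoxide, had a log2 ratio of 0.88 ± 0.19, the isopentenyl diphosphate isomerase gene Idi1 0.84 ± 0.20 and the mevalonate pathway gene Pmvk 0.48 ± 0.11 (SE, n = 3), which was −0.028 with median centring, where the median of all genes was −0.22. Within slide 2, 19 members rose and 2 fell, with Msmo1 at 1.40 ± 0.04 (SE, n = 2). Medians were 0.51 and 0.41 on slide 2 and 0.03 on replicate 3, and 0.34 with the slide as a block (adjusted p = 6.03e-05, and adjusted p = 0.504 with an estimated correlation).

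The list of the unfolded protein and integrated stress response shifted up with *B. clausii*, where 7 of 32 members rose, 0 fell and 25 did not pass. Adjusted over the list alone 17 rose and 3 fell, and the median was 0.28 (adjusted p = 0.00116, and adjusted p = 0.402 with an estimated correlation). The endoplasmic reticulum chaperone genes Hyou1 and Hspa5 had log2 ratios of 0.63 ± 0.10 (SE, n = 3) and 0.47 ± 0.08 (SE, n = 2), and Hspa5 had −0.14 with median centring, where the median of all genes was −0.22. Manf had 0.58 ± 0.10 (SE, n = 3). Among immediate early genes 3 of 27 rose, 0 fell and 24 did not pass, and 9 rose and 1 fell adjusted over the list alone (median 0.22, adjusted p = 0.0102, and adjusted p = 0.402 with an estimated correlation). These were the transcription factor genes Jund (0.94 ± 0.18), Maff (0.45 ± 0.11) and Fosb (0.33 ± 0.08). Within slide 2, 16 members rose and 4 fell, and among the falls Fos fell by 1.31 ± 0.04 and the phosphatase gene Dusp6 by 1.48 ± 0.04 (SE, n = 2). On replicate 3 the medians were 0.02 for the stress response and 0.01 for the immediate early genes. A slide block gave 0.19 (adjusted p = 0.00186) and 0.22 (adjusted p = 0.0152), with adjusted p = 0.504 for each with an estimated correlation.

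The NRF2 and oxidative stress list shifted down with *B. clausii* while single members went both ways. Of 27 members 2 rose, 2 fell and 23 did not pass, and 4 rose and 12 fell adjusted over the list alone (median −0.22, adjusted p = 0.0102, and adjusted p = 0.402 with an estimated correlation). The superoxide dismutase gene Sod1 rose by 0.52 ± 0.10 and the peroxiredoxin gene Prdx5 fell by 0.61 ± 0.13 (SE, n = 3). The ferritin gene Fth1, also called as a rise, was saturated in both channels on slide 2. Within slide 2 the catalase gene Cat fell by 1.03 ± 0.04 and Prdx1 by 0.93 ± 0.05 (SE, n = 2). The list median was −0.02 on replicate 3 and −0.23 with the slide as a block (adjusted p = 0.0189, and adjusted p = 0.504 with an estimated correlation).

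Ribosomal protein genes had a median log2 ratio of 0.28 with *B. clausii*, and saturation on slide 2 affected 22 of the 37 members. The list passed (adjusted p = 0.0154, and adjusted p = 0.402 with an estimated correlation), with 3 members that rose, 2 that fell and 32 that did not pass, and with 19 rises and 5 falls adjusted over the list alone. The rises included Rplp1 and Rpl5, both at the ceiling in both channels on slide 2, and the falls included Rpl18, which had −0.68 and −0.43 on replicates 2 and 3 and was saturated in Cy3 on replicate 1. The 15 members never saturated had a median of −0.17, and the list then did not pass (adjusted p = 0.0558). A slide block gave all members a median of 0.21 (adjusted p = 0.00899, and adjusted p = 0.504 with an estimated correlation), and it was 0.03 on replicate 3.

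Other gene lists did not pass with *B. clausii* over all 8 arrays. The NF-kB pathway list had a median of −0.05 with 4 falls (adjusted p = 0.324), pattern recognition receptors one of −0.18 with 1 fall (adjusted p = 0.0682) and autophagy genes one of −0.19 with 2 falls (adjusted p = 0.0682). Of the glycolysis and hypoxia genes 6 rose and 2 fell (adjusted p = 0.201). Markers of osteoclasts (adjusted p = 0.293), dendritic cells (0.148), neutrophils (0.846), lymphocytes (0.363), fibroblasts (0.485) and epithelial cells (0.285) did not pass. Within slide 2, 4 more lists shifted down, namely pattern recognition receptors (6 rises and 20 falls, adjusted p = 0.0168), autophagy (3 and 13, adjusted p = 0.026), fatty acid oxidation (4 and 15, adjusted p = 0.0168) and apoptosis (4 and 18, adjusted p = 0.0209). Each lost its call with an estimated correlation (adjusted p = 0.296 to 0.497 with an estimated correlation), and none passed with the slide as a block (adjusted p = 0.0666 to 0.115). Median centring of the arrays in place of loess moved the median of all genes by 0.13 with *L. acidophilus*, −0.21 with *B. clausii* and −0.34 with *B. bifidum*. Relative to the median of all genes with that centring, each list called with *B. clausii* kept its sign, but the lists that had shifted up lay nearer to 0. Their relative medians went from 0.29 to 0.016 for ribosomal proteins, 0.29 to 0.057 for the stress response, 0.23 to 0.10 for immediate early genes and 0.33 to 0.21 for cholesterol biosynthesis.

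**Figure D2:**
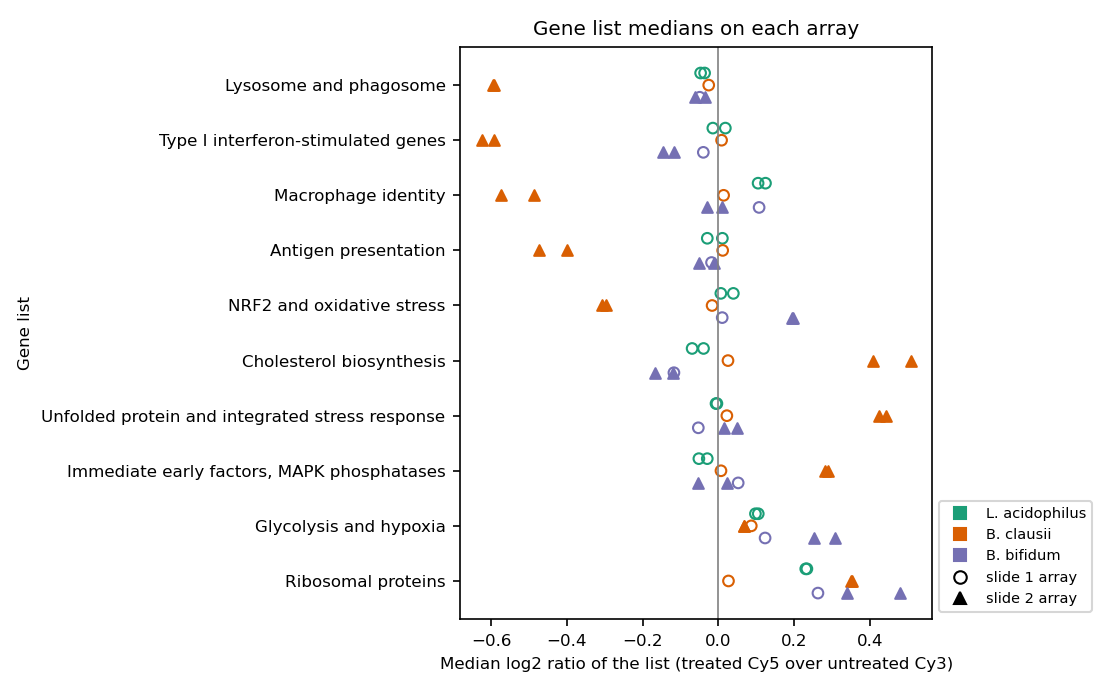
Median log2 ratio (Cy5 over Cy3) of 10 gene lists on each of the 8 arrays, with open circles for slide 1 and filled triangles for slide 2. For *B. clausii* the lysosome list lies at −0.59 on both slide 2 arrays and at −0.03 on slide 1, the slide 2 values of ribosomal protein genes include saturated spots, and with median centring the *B. bifidum* medians of the glycolysis list (−0.07) and the NRF2 list (−0.19) lie below that of all genes.

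The comparison of *B. bifidum* with untreated cells gave 77 genes that rose and 186 that fell. The chemokine gene Ccl2, which recruits monocytes, rose by a log2 ratio of 0.60 ± 0.06, or 1.51-fold (SE, n = 3, adjusted p = 0.00743), with 0.62, 0.63 and 0.54 on the 3 arrays, and was −0.020 with median centring, where the median of all genes was −0.35. The chemokine gene Ccl4 fell by 1.06 ± 0.21 (SE, n = 3, adjusted p = 0.0471), with −1.32, −1.33 and −0.53. The largest fall was that of Rnf20, a ubiquitin ligase of histone H2B, at −1.48 ± 0.22 (SE, n = 3, adjusted p = 0.022). The Golgi protein genes Golgb1 and Trip11 had −1.29 ± 0.17 and −1.15 ± 0.12, and Dicer1, which processes microRNA precursors, −1.24 ± 0.23 (SE, n = 3). Fam102b had −1.08 ± 0.18, Tnrc18 −0.997 ± 0.17 and Ubap2l −0.98 ± 0.11, and the probes of Golgb1 and Ubap2l disagreed. With only probes above background in both channels on all arrays, another probe stood for Golgb1 and had 0.31.

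Among the rises with *B. bifidum*, Ptma had a log2 ratio of 0.84 ± 0.10 (SE, n = 3, adjusted p = 0.013), though its probes ranged from −0.51 to 0.84. The RNA helicase gene Dhx9 had 0.75 ± 0.11 and Ndrg4 0.72 ± 0.10 (SE, n = 3). Rplp1, Aldoa, S100a4 and Ftl1 were also called as rises and were saturated in both channels on slide 2, Rplp1 on 1 array of the strain and the others on 2. On replicate 3, where they were not saturated, they had 0.96, 0.60, 0.56 and 0.55. Rpl41, also called, had 0.92 on replicate 3, and its ratios on slide 2 (0.62 and 0.72) were upper bounds because Cy3 was saturated. Of the 263 calls 254 had the same sign on all arrays of the strain, 6 lay beyond a log2 ratio of 1 in size, and 20 were of genes with saturated spots.

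With the slide as a block, 604 genes rose and 1524 fell with *B. bifidum*. Of these 2128 calls, 1686 had the same sign on all arrays of the strain. Within slide 2, 2295 rose and 3598 fell. Within slide 1 the strain had 1 array and the spread came from the 2 *L. acidophilus* arrays alone, so no count is given. The count was 0 without replicate 1 or 2 (limma, with 1252 and 1405 genes at an unadjusted p under 0.05) and 2089 without replicate 3. It was 23 without either *L. acidophilus* array, 61, 62 and 1409 without *B. clausii* replicates 1, 2 and 3. Ptma, Trip11, Ubap2l and Ccl2 passed without each of the *L. acidophilus* and *B. clausii* arrays in turn and without replicate 3, and none of them passed without replicate 1 or 2. Rises made up 29.3% of the calls, against 0% of the 1, 3 and 3 calls made with the scanner's processed signals, with the deposited matrix and with median centring, which are too few calls to measure a share. They made up 28.6% of 192 calls without background correction and 28.9% of 266 with Aquantile. Limma called 0 genes with only the arrays of *B. bifidum* and 0 with same-slide arrays averaged, at 2723 and 575 genes with an unadjusted p under 0.05, and 131 with a robust intensity trend.

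Other genes of the fixed inflammatory set did not pass with *B. bifidum* over all 8 arrays. Tnf had a log2 ratio of −0.28 ± 0.08 (SE, n = 3, adjusted p = 0.0964) and Cxcl10 one of −0.43 ± 0.22 (SE, n = 3, adjusted p = 0.332). Tlr2 had −0.24, Ptgs2 −0.18, Il1b −0.13 and Il6 −0.12, and Tlr4, Cd14, Nos2, Il10 and Arg1 lay between −0.04 and 0.12. Within slide 2, Cxcl10 fell by 0.54 ± 0.05, Tlr2 by 0.37 ± 0.04 and Tnf by 0.23 ± 0.04 (SE, n = 2). On replicate 3 they had −0.21, 0.01 and −0.38. The lists of proinflammatory cytokines and enzymes (median −0.10), chemokines (−0.06), NF-kB pathway genes (−0.06) and interferon-stimulated genes (−0.09) did not pass (adjusted p = 0.796 for each).

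The glycolysis and hypoxia list shifted up with *B. bifidum*, although with median centring its median lay 0.07 below that of all genes (relative median −0.07). Of 34 members 2 rose, 1 fell and 31 did not pass, and 7 rose and 2 fell adjusted over the list alone (median 0.22, adjusted p = 0.000365, and adjusted p = 0.323 with an estimated correlation). The rises were the saturated gene Aldoa and the hypoxia-inducible mitophagy gene Bnip3 (0.60 ± 0.08, and −0.057 with median centring, where the median of all genes was −0.35), and Hif1a, which encodes a subunit of the hypoxia-inducible factor, fell by 0.40 ± 0.08 (SE, n = 3). Within slide 2, Adm rose by 0.89 ± 0.04 and Slc2a1 by 0.68 ± 0.05 (SE, n = 2). The list median was 0.31 and 0.25 on slide 2 and 0.12 on replicate 3, and with the slide as a block it was 0.13 (adjusted p = 4.51e-05, and adjusted p = 0.253 with an estimated correlation). Without saturated genes 28 members had a median of 0.09 and the call ended (adjusted p = 0.0705).

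The NRF2 and oxidative stress list shifted up with *B. bifidum*, and with median centring its median lay below that of all genes (relative median −0.19). Of 27 members 1 rose, the saturated ferritin gene Ftl1, 0 fell and 26 did not pass, and 3 rose adjusted over the list alone (median 0.12, adjusted p = 0.0225, and adjusted p = 0.967 with an estimated correlation). Fry gave an unadjusted p of 0.117. Within slide 2 the haem oxygenase gene Hmox1 rose by 0.85 ± 0.06 and G6pdx fell by 0.69 ± 0.04 (SE, n = 2). The list median was 0.01 on replicate 3 and 0.15 with the slide as a block (adjusted p = 0.0202, and adjusted p = 0.904 with an estimated correlation). Without saturated genes 25 members had a median of 0.11 and the call ended (adjusted p = 0.108).

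Ribosomal protein genes had a median log2 ratio of 0.37 with *B. bifidum* (adjusted p = 2.37e-07, and adjusted p = 0.393 with an estimated correlation). Of 37 members 4 rose, 1 fell and 32 did not pass, and 20 rose and 3 fell adjusted over the list alone. Rpl19, saturated in Cy3 on replicate 1, had 0.55 and 0.54 on replicates 2 and 3 and −0.18 with median centring, where the median of all genes was −0.35, and Rpl30, never saturated, fell by 0.61 ± 0.10 (SE, n = 2). The 15 members never saturated had a median of 0.03 (adjusted p = 0.912), and the slide block gave the whole list a median of 0.32 (adjusted p = 9.45e-09, and adjusted p = 0.715 with an estimated correlation). The relative median of the whole list was 0.38 with loess and 0.023 with median centring. Camera called 0 lists with *B. bifidum* from the scanner's processed signals and 0 from the deposited matrix, with 3 and 3 at an unadjusted p under 0.05. Cholesterol biosynthesis genes had a median of −0.12 and did not pass (adjusted p = 0.0779), but passed with the slide as a block (adjusted p = 0.0202, and adjusted p = 0.935 with an estimated correlation). Of the heat shock protein genes 3 rose (adjusted p = 0.491 for the list), and the marker lists of other cell types did not pass (adjusted p = 0.111 to 0.796).

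*B. clausii* was then compared with *B. bifidum*. Ddit4, a stress-induced inhibitor of mTOR signalling, was higher with *B. clausii* by a log2 ratio of 1.89 ± 0.15 (SE, adjusted p = 0.0154) and the splicing factor gene U2surp by 0.90 ± 0.10 (SE, adjusted p = 0.0359). Plin2 was lower by −2.26 ± 0.15 (SE, adjusted p = 0.0067) and Npc2 by −1.10 ± 0.11 (SE, adjusted p = 0.0375). For Ddit4, Plin2 and Npc2 the value of *B. clausii* replicate 3 was missing, so these rest on 2 arrays against 3. U2surp rested on 3 against 3, whose values did not overlap, as chance gives for 10% of genes of such groups. Baz1b (0.81), Ubap2l (1.15), Cxcl2 (1.06), Gabarapl1 (−0.99), Rnf149 (−0.71) and H2bc4 (−0.56) had the next smallest p and did not pass. These 4 calls compare with 148 rises and 90 falls with the slide as a block and 2270 and 2236 within slide 2. Within slide 1 each strain had 1 array and the spread came from the 2 *L. acidophilus* arrays alone, so no count is given. The 4 calls became 0 without *B. clausii* replicate 1 or 2 or *B. bifidum* replicate 2 (limma, 890, 901 and 990 genes at an unadjusted p under 0.05), 2139 without *B. clausii* replicate 3 and 467 without *B. bifidum* replicate 3. Limma called 0 genes with median centring (307 at an unadjusted p under 0.05) and with same-slide arrays averaged (105). Plin2 passed without *L. acidophilus* replicate 1 or 2 or *B. bifidum* replicate 1, and U2surp, Ddit4 and Npc2 did not.

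Within slide 2, where both strains had 2 arrays, Chac1 was higher with *B. clausii* than with *B. bifidum* by 3.00 ± 0.07 and Zbtb32 by 2.32 ± 0.07, and Fam20c was lower by −2.44 ± 0.07 (SE, n = 2 and 2). The urokinase gene Plau was lower by −2.18 ± 0.06, the cathepsin gene Ctsd by −1.64 ± 0.08, Hmox1 by −1.86 ± 0.09 and the interferon regulatory factor gene Irf7 by −1.58 ± 0.06. Selenbp1 and Selenbp2 were lower by −2.67 ± 0.08 and −2.65 ± 0.07, and these near-identical genes are uncertain, since their probes were not checked for shared binding. The sterol transporter gene Stard4 was higher by 1.80 ± 0.08 and the cathepsin gene Ctsc by 1.16 ± 0.07. Osteoclast markers, a list of another cell type, shifted down within slide 2 as well, with 6 falls and 1 rise (median −0.26, adjusted p = 0.0108), among them Acp5 at −1.16 ± 0.07. That list lost its call with an estimated correlation, as did each other list within slide 2 for this comparison (adjusted p = 0.176 to 0.532 with an estimated correlation).

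The list tests between strains were chosen after seeing the data. Over all 8 arrays, 12 lists differed between *B. clausii* and *B. bifidum* (adjusted p = 0.361 to 0.419 with an estimated correlation). The cholesterol biosynthesis list was higher with *B. clausii* (median difference 0.43, adjusted p = 8.65e-12), with 0 members past the threshold over all genes and 13 higher adjusted over the list alone. The lysosome list (−0.37, adjusted p = 9.58e-12), interferon-stimulated genes (−0.29, adjusted p = 1.92e-08) and the NRF2 list (−0.29, adjusted p = 2.85e-08) were lower, and in the NRF2 list 10 members were lower and 1 higher adjusted over the list alone. The stress response list (0.20, adjusted p = 0.00109) was higher. Within slide 2, cholesterol biosynthesis genes had a median difference of 0.63, with 20 higher and 0 lower, and the lysosome list one of −0.56, with 2 higher and 35 lower. On slide 1, with 1 array per strain, the lysosome medians were −0.025 with *B. clausii* and −0.049 with *B. bifidum*. In the same order, interferon-stimulated genes had 0.009 and −0.040 there and the NRF2 list −0.016 and 0.010. Cholesterol biosynthesis genes had 0.025 and −0.117, and the stress response list 0.023 and −0.053. The ribosomal list was called too (−0.08), but its difference relative to all genes was 0.11 with median centring and 0.03 with the scanner's processed signals, and it did not pass without saturated genes (adjusted p = 0.0921).

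In the comparison of *L. acidophilus* with *B. clausii*, Plin2 was higher with *L. acidophilus* by a log2 ratio of 2.50 ± 0.16 (SE, adjusted p = 0.00613) and Ddit4 was lower by −2.32 ± 0.17 (SE, adjusted p = 0.00651). Both rest on 2 arrays against 2, since replicate 3 of *B. clausii* gave no value, and these arrays lay on different slides. The 2 calls became 0 without *B. clausii* replicate 1 or 2 (limma, 551 and 524 genes at an unadjusted p under 0.05), 2584 without replicate 3 and 38 without *L. acidophilus* replicate 1. Ddit4 did not pass without *L. acidophilus* replicate 2, and was 0.33 in the Cy5 channel alone. Limma called 0 genes with median centring (4990 at an unadjusted p under 0.05), with only the arrays of these strains (1318) and with same-slide arrays averaged (113). Npc2 (1.18), Gabarapl1 (1.27), Clec4d (0.76), H2-Oa (0.59), Clpp (−0.80), Cxcl2 (−0.89) and Rnf113a1 (−0.82) did not pass, nor did Slc39a5 (−0.66), which was not well above background in Cy5 with *B. clausii*. Within slide 1 *B. clausii* had 1 array and the spread came from the 2 *L. acidophilus* arrays alone, so no count is given. Of the lists 8 differed, each with adjusted p = 0.646 with an estimated correlation. Among them the lysosome list was higher with *L. acidophilus* (0.33, adjusted p = 1.58e-07) and the cholesterol biosynthesis list was lower (−0.36, adjusted p = 9.12e-07). A slide block gave 0.23 (adjusted p = 6.27e-05) and −0.23 (adjusted p = 6.24e-05), with adjusted p = 0.804 for each with an estimated correlation. On slide 1, the lysosome medians were −0.036 and −0.047 with *L. acidophilus* against −0.025 with *B. clausii*, and the cholesterol medians −0.069 and −0.039 against 0.025.

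No gene differed between *L. acidophilus* and *B. bifidum* (limma, 0 of 15296, with 581 at an unadjusted p under 0.05). The smallest p were those of Baz1b (0.76), the transcription factor gene Mitf (0.81), U2surp (0.65), Eif3l (0.76) and Sertad2 (0.61) with higher values for *L. acidophilus*, and of Emilin2 (−0.65), the lectin receptor gene Clec4e (−0.74), Rab1a (−0.61), Mmp19 (−0.48) and Slc39a5 (−0.65) with lower ones, each with an adjusted p of 0.832. Slc39a5 was not well above background in Cy5 with *B. bifidum*. Limma called 0 genes with the slide as a block, with 941 at an unadjusted p under 0.05. Within slide 1 *B. bifidum* had 1 array and the spread came from the *L. acidophilus* arrays alone, so no count is given. Leaving out *B. bifidum* replicate 3 gave 242 calls and leaving out *L. acidophilus* replicate 1 gave 32. No list differed over all 8 arrays. With the slide as a block 8 lists did, among them the interferon-stimulated genes (−0.18, adjusted p = 2.66e-05, and adjusted p = 0.757 with an estimated correlation). That block takes the slide effect of *L. acidophilus* from the other strains, and on slide 1 the medians of these genes were 0.019 and −0.015 with *L. acidophilus* against −0.040 with *B. bifidum*.

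The calls of *B. clausii* and *B. bifidum* overlapped. Over all 8 arrays 32 genes rose with both and 37 fell with both, against 1.66 and 4.82 for independent lists of those sizes. Another 2 genes were called in opposite directions. Both strains lay on the same slides with the same dye orientation, so a dye or slide effect can give overlap without a response. The values for independent lists therefore do not show that the overlap is a shared response. Saturated genes made up 17 of the 330 rises with *B. clausii* and 19 of the 77 with *B. bifidum*. In each strain 13 of them were saturated in both channels. How many of the 32 shared rises were of saturated genes was not counted, so saturation may account for part of them. Within slide 2, 1400 genes rose with both and 2300 fell with both, against 589 and 1086, and 791 were called in opposite directions. Rcor3, a corepressor gene, fell with both (−1.95 ± 0.08 and −1.86 ± 0.08, SE, n = 2), whereas Hmox1 had −1.01 and −1.01 with *B. clausii* and 0.75 and 0.95 with *B. bifidum*. Across 15266 genes the slide 2 ratios of the strains correlated at r = 0.52, and 20 simulations of unchanged cells against shared untreated RNA gave r = 0.67. They called 0.05 genes per strain on average, with 0 shared rises and 0.05 shared falls, too few to say anything about the overlap. The covariance was 0.0547 against a simulated 0.00568, a difference of 0.0490. The simulated reference was given the spread of the treated RNA, taken from differences between arrays of the same strain. Such differences hold nothing of untreated RNA shared by those arrays. These settings fixed the simulated correlation and covariance, so the difference does not measure covariance beyond shared untreated RNA. The untreated channel could not be split from its arrays, so part or all of the covariance may come from shared untreated RNA.

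Intensities in the untreated Cy3 channel differed between the slides, which were scanned with different ranges. They were taken after loess and Aquantile, which gives all arrays the same distribution of brightness averaged over the channels. The mean log2 Cy3 intensity of Il1b was 5.26 higher on slide 1 than on slide 2, that of Ptgs2 3.64, Ccl2 2.87, Il6 2.00, Nos2 1.95 and Tnf 1.24. Arg1 had 11.61 ± 0.58 (SD, n = 4) on slide 1 and was well above background on 1 of 4 slide 2 arrays, so no difference is given. The slide 2 means of Il1b (6.60), Il6 (6.52) and Nos2 (6.79) lay near the 6.64 of Arg1. These genes were well above background on 4 of 4 slide 2 arrays, but the size of their differences is uncertain. Tlr2 was lower by −0.72 and Tlr4 by −0.61. The median difference was 1.35 over 18 proinflammatory cytokines and enzymes and −2.56 over 41 interferon-stimulated genes. Anti-inflammatory genes (0.56), macrophage identity genes (0.45) and markers of osteoclasts, another cell type (0.53), were also higher on slide 1, and heat shock protein genes (−0.45) were lower. Without *B. clausii* replicate 3 the median of the heat shock protein genes was −0.19. Each ratio to untreated cells reported above is relative to the untreated RNA of its own array.

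**Figure D3:**
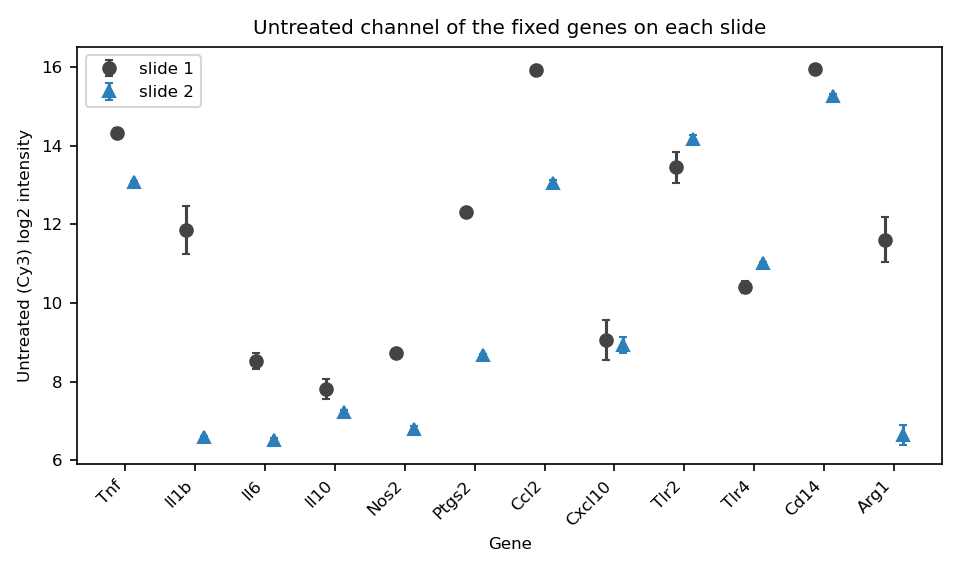
Mean log2 Cy3 intensity, after loess and Aquantile, of the 12 fixed genes in untreated cells on slide 1 and slide 2. Error bars give the SD of 4 arrays per slide. Il1b and Ptgs2 lie 5.26 and 3.64 higher on slide 1, and Tlr2 and Tlr4 lie lower by −0.72 and −0.61. The slide 2 point of Arg1 includes arrays on which it was not well above background, and that of Il1b lies near it.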

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

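The tests on the slides described here were chosen after the result was seen, and the count over other splits of the arrays was planned. Within *B. clausii*, log2 ratios differed between slide 2 and slide 1 for 5841 of 15218 genes past an adjusted p of 0.05 by limma, and within *B. bifidum* for 4512 of 15241. Each slide 1 group was a single array of the strain, assumed to vary like the others, and the spread came from pairs of arrays of the same slide, which may be technical. These counts therefore compare the arrays at hand and do not show that the slides differ beyond the spread between cultures. Among genes called within slide 2 beyond a log2 ratio of 1 in size, 48.4% had the same sign on *B. clausii* replicate 3 and 53.2% on *B. bifidum* replicate 3.

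The pattern was that the ratios of a strain on slide 2 were not seen again on slide 1. Weak signal on *B. clausii* replicate 3 is argued against as the whole cause, because the slide 2 mean of *B. bifidum* correlated with *B. bifidum* replicate 3 at r = −0.0242 with no *B. clausii* array involved. A swap of strain labels among the slide 1 arrays is argued against too, because no slide 1 array correlated with the slide 2 mean of another strain above r = 0.133. A signal shared by the slide 1 arrays whatever the strain may contribute, since slide 1 arrays of different strains correlated at r = 0.599 or more. A response common to the strains on both slides is argued against, because different strains on different slides correlated at r = −0.07 to 0.15. A common response confined to slide 1 would look like such a signal and stays open. The design names no biological group for the slides, so no biological explanation was tested.

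For *B. clausii* against *B. bifidum*, the split of the 6 arrays by strain gave 4 genes and was 1 of 10 splits with as many. The highest count among the other splits was 0. There are too few splits for a share under 0.05.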

How the results depend on the processing

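Fits of a single slide, averaging of same-slide arrays and leaving out saturated spots were chosen after seeing the data, and the other alternatives were planned. The main counts were 0 genes for *L. acidophilus*, 726 for *B. clausii*, 263 for *B. bifidum*, 4 for *B. clausii* against *B. bifidum*, 2 for *L. acidophilus* against *B. clausii* and 0 for *L. acidophilus* against *B. bifidum*, with 1, 9 and 3 lists for the strains in that order. Of 230 recomputed counts 130 stayed within 1.5 times. Of 3229 recomputed values of named genes 2245 kept their side of the threshold, 858 lost the call and 119 gained it. A further 7 changed sign with a call in the main fit or in the alternative. A change of sign without a call in either fit was counted among those that kept their side. The cause of the changes below was not tested, except where stated. Of the 8 arrays, *B. clausii* replicate 3 had the fewest probes well above background in at least 1 channel (13373).

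Without background correction *B. clausii* had 194 calls and *B. clausii* against *B. bifidum* 2. From the scanner's processed signals *B. clausii* had 44 and *B. bifidum* 1, with 0 for *B. clausii* against *B. bifidum*, 0 for *L. acidophilus* against *B. clausii* and 0 lists for *L. acidophilus* and for *B. bifidum*. From the deposited matrix *B. clausii* had 69, *B. bifidum* 3 and *L. acidophilus* against *B. bifidum* 1, with 0 for the other pairs of strains and 0 lists for *L. acidophilus* and for *B. bifidum*. Median centring gave *B. clausii* 0 (limma, 4861 genes at an unadjusted p under 0.05), *B. bifidum* 3 and 0 for *B. clausii* against *B. bifidum* and *L. acidophilus* against *B. clausii*, with 10 lists for *L. acidophilus* and 11 for *B. bifidum*. It turned the sign of Pmvk (−0.028) and Hspa5 (−0.14) with *B. clausii* and Ccl2 (−0.020), Bnip3 (−0.057) and Rpl19 (−0.18) with *B. bifidum*, against medians of all genes of −0.22 and −0.35, above which these genes stayed. Aquantile, which leaves the ratios of an array unchanged, gave 723 and 266.

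The strict filter on dim probes reversed Golgb1 with *B. bifidum* (0.31), by choosing another probe. The mean of a gene's probes gave 4 genes and 2 lists for *L. acidophilus* and 392 for *B. clausii*. The Cy5 channel alone gave 0 for *B. clausii* against *B. bifidum* and for *L. acidophilus* against *B. clausii*, with Ddit4 reversed in the latter (0.33). Camera with an estimated correlation called 0 lists for each strain. The robust intensity trend gave 79 for *B. clausii*, 131 for *B. bifidum* and 2 for *B. clausii* against *B. bifidum*. A minimum log2 ratio of 1 gave 20 and 6 for these strains, and testing each probe gave 444 for *B. bifidum*.

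Replicate numbers did not pair the arrays. Deviations of same-numbered *B. clausii* and *B. bifidum* arrays correlated at 0.407, 0.298 and 0.462, those of *L. acidophilus* with *B. clausii* at −0.0835 and −0.0889, and *B. clausii* replicate 2 correlated better with *B. bifidum* replicate 1 (0.373) than with its own number. The replicate block gave 505 calls for *L. acidophilus*, 4345 for *B. clausii*, 2275 for *B. bifidum*, 3101 for *L. acidophilus* against *B. clausii* and 1430 for *L. acidophilus* against *B. bifidum*. With this block the ribosomal list was not called with *L. acidophilus* (adjusted p = 0.141), and the proinflammatory list was, downward (median −0.16, adjusted p = 0.0226, and adjusted p = 0.964 with an estimated correlation). The NRF2 list was not called with *B. bifidum* (adjusted p = 0.0696). In these data the replicate numbers partly follow the slides.

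The slide block gave 420 genes and 4 lists for *L. acidophilus*, whose slide effect it takes from the other strains, 3851 for *B. clausii*, 2128 for *B. bifidum* and 238 for *B. clausii* against *B. bifidum*. Slide 2 alone gave 8543, 5893 and 4506 for the last 3. Slide 1 alone left 1 array each for *B. clausii* and *B. bifidum*, with the spread from the *L. acidophilus* arrays, so no counts are given for them here. With only the strains compared, limma gave 0 for *B. clausii*, 0 for *B. bifidum*, 1 for *B. clausii* against *B. bifidum* and 0 for *L. acidophilus* against *B. clausii*, with 3031, 2723, 1427 and 1318 genes at an unadjusted p under 0.05. Averaging same-slide arrays gave 0 in all 6 comparisons, with 155, 695, 575, 105, 113 and 84 genes at an unadjusted p under 0.05. Without saturated spots *L. acidophilus* and *B. bifidum* had 0 lists, and the strains had 0, 689 and 223 genes.

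Leaving out each array in turn gave 0 to 59 genes and 1 to 2 lists for *L. acidophilus*, 0 to 5486 genes and 8 to 12 lists for *B. clausii* and 0 to 2089 genes and 2 to 4 lists for *B. bifidum*. Between strains the ranges were 0 to 2139 for *B. clausii* against *B. bifidum*, 0 to 2584 for *L. acidophilus* against *B. clausii* and 0 to 242 for *L. acidophilus* against *B. bifidum*. The lowest gene counts for *B. clausii* and *B. bifidum* came without replicate 1 or 2 of the strain and the highest without its replicate 3. For lists, *B. clausii* had 8 without *B. bifidum* replicate 3 and 12 without its own replicate 3, and *B. bifidum* had 2 without its replicate 2 and 4 without replicate 3 of either strain. Where *L. acidophilus* was left with 1 array, that array was assumed to vary like the others.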

Other observations

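The tests of the ribosomal pattern against saturation, by strain and by slide, and those of the untreated channel were chosen after the result was seen, and the pooled brightness test was written before. Further gene groups moved within slide 2. The cell cycle list shifted down with *B. bifidum* there, with 5 rises and 24 falls (median −0.15, adjusted p = 0.0309, and adjusted p = 0.616 with an estimated correlation). Kif20a, a mitotic kinesin gene, had a log2 ratio of −0.60 ± 0.04 and Pcna, a replication clamp gene, 0.71 ± 0.05 (SE, n = 2). The fatty acid oxidation list was lower with *B. clausii* than with *B. bifidum* within slide 2, with 4 members higher and 9 lower (median −0.15, adjusted p = 0.0188, and adjusted p = 0.246 with an estimated correlation), and the carnitine transfer gene Cpt1a differed by −0.84 ± 0.06 (SE, n = 2 and 2). With *B. clausii* the noncoding RNA genes Rmrp and Neat1 rose by 2.07 ± 0.05 and 1.92 ± 0.04 and the sterol exporter gene Abcg1 fell by 2.35 ± 0.04. With *B. bifidum* the signalling kinase gene Irak2 rose by 1.28 ± 0.05 and Fnip2 by 1.42 ± 0.04 (SE, n = 2).

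Some values followed the slide. The granulin precursor gene Grn lay between −2.32 and −1.49 on the slide 1 arrays and between 0.91 and 1.36 on the slide 2 arrays. Lars2, saturated in Cy5 on slide 2, lay between −1.58 and −1.15 on slide 1. H2ac13 and H2ac15 lay between −0.85 and −0.59 on all 8 arrays.

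Ribosomal protein genes had a median above 0 on 8 of 8 arrays. The list lay at percentile 99.91 of lists matched on brightness for the mean of the strains, 98.28 for *B. clausii* and 99.51 for *B. bifidum*, but 22 of its 37 members were saturated on slide 2, so these values do not decide on a brightness effect. Saturation may account for the slide 2 part, since the 15 members never saturated lay at percentile 34.72 of matched unsaturated genes there with a median of −0.05, although leaving out saturated members also leaves out the brightest. On slide 1, with no saturated spot, the list had a median of 0.21 at percentile 95.17, and *L. acidophilus* lay at 94.06, within the range that brightness could give, with *B. clausii* replicate 3 at 34.87 and *B. bifidum* replicate 3 at 98.83. A probe-specific dye effect stays open, because all 8 arrays have the same dye orientation and it cannot be told apart from a response to the bacteria.

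The proinflammatory list was brighter in the untreated channel of slide 1 than of slide 2. It was not the only such list. Among others, anti-inflammatory genes (0.56, percentile 100), macrophage identity genes (0.45, percentile 99.96) and osteoclast markers (0.53, percentile 99.71) also lay above lists matched on brightness. The wider scan range of slide 1 is unlikely as the whole cause, because the difference of the proinflammatory list lay at percentile 100 of lists matched on brightness. These intensities came after loess and Aquantile, so an effect of the scan range on all probes alike was removed before that test. Weak signal on *B. clausii* replicate 3 is argued against as well for the proinflammatory list, because its median difference was 1.48 without that array. Interferon-stimulated genes went the other way, with a median difference of −2.56, as did heat shock protein genes (−0.45, percentile 0.93). Without *B. clausii* replicate 3 these medians were −2.30 and −0.19. The heat shock value then lay within its matched range of −0.39 to 0.13, so that difference may rest on this array. Separate untreated cultures in different states stay open and were not tested, since the design names no group for the slides.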
